A study of Rattus norvegicus and Homo sapiens with 16 samples.

How the data were processed

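The series holds 16 libraries from 2 culture systems. Rat insulinoma cells, an insulin-secreting line, gave 4 untreated libraries (1 to 4) and 4 libraries exposed to IL-1β (5 to 8). Isolated human pancreatic islets gave 4 untreated libraries (9 to 12) and 4 libraries exposed to IL-1β (13 to 16). Per the labels' protocols, recombinant IL-1β of the matching species was given at 1 ng/mL for 3 h in medium without serum. RNA was extracted with Trizol from the rat cells and with a Qiagen column kit from the islets, so extraction and species changed together between the systems. Libraries were made with the SOLiD SAGE kit, per the labels' protocols. This method sequences 1 short tag near the 3′ end of each transcript, so a gene's count does not grow with its length. The labels gave no donor, culture or batch, and library numbers were shared by no groups.

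The authors deposited a table of tag counts per gene symbol for each organism, with 1 column per library, and the values were whole numbers with a different total in each library. The submitters' processing notes name the builds GRCh38 and Rnor_6.0. The aligner and the counting program are not given in the sources used here. Both count tables hold all 16 libraries; rat libraries were analysed in the rat table and islet libraries in the human table. The human table also lists 3 named alleles, all at 0 counts, which were left out. The authors also deposited, per the file headers, normalized signal values per library, which are counts divided by a size factor per library, and their means. In the same tables the authors deposited log2 fold changes, standard errors and test statistics given here as scores, and p-values from DESeq2, whose version is not given in the sources used here. The submitters' filter on low counts for these tables is also not given in the sources used here. Every normalized value was a whole multiple of 1 read within a tolerance of 0.01, and the recovered reads were used as an alternative input. They equalled the deposited count for 25.6% of rat and 32.0% of islet values. Their totals were 7.60% to 13.1% higher in rat cells and 7.45% to 16.5% higher in islets than the deposited counts of the same genes. The authors' normalized tables therefore rest on another count than the deposited count tables, and the reason is not given in the sources used here.

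Totals per library were 5112483 to 8395162 counts in rat cells and 6285589 to 11512141 in islets. No pair of libraries within an arm was a duplicate: chi-square per degree of freedom over genes with at least 20 counts in the pair ranged from 19.5 to 81.2. Genes were filtered with filterByExpr at a minimum count of 10, which left 9858 rat and 11772 islet genes. Counts were scaled by TMM, and each system was fitted separately with edgeR's quasi-likelihood test with robust dispersions, with treatment as the only term. P-values were adjusted by the Benjamini-Hochberg method, and genes with adjusted p under 0.05 were called. CPM values are TMM-scaled, and log2 fold changes used the fitted model. Standard errors (SE) are Wald errors from the model's weights and the gene's posterior quasi-dispersion, and they have no value where an arm was at 0. Where all untreated libraries were at 0, a fold is a lower bound against a floor of 3 counts over the arm; with 1 to 3 counts the ratio is given with an exact 95% counting interval. Such intervals and floors cover counting error only.

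The response was compared between systems for 6862 genes matched by symbol and tested in both, with an interaction term in 1 edgeR model. Overlap of calls was tested with Fisher's exact test, two-sided, against lists drawn independently. Gene lists fixed in advance were tested with camera at a preset correlation of 0.01, for lists with at least 5 tested members, and again with the correlation estimated from the data and with fry. The lists were chemokines, cytokines and growth factors, NF-kB components and feedback, the interleukin-1 and Toll-like receptor pathway, immediate early genes, antigen presentation, acute phase and STAT3 genes, adhesion and matrix remodelling, nitric oxide and oxidative defence, apoptosis and survival, beta cell transcription factors, beta cell function and secretion, unfolded protein response, glycolysis and glucose uptake, nuclear encoded mitochondrial respiratory chain, mitochondrially encoded genes, proliferation and heat shock genes. A further list, counted among the lists tested and called, is not reported here. Markers of alpha, delta and PP cells, acinar cells, ductal cells, stellate cells and fibroblasts, endothelium, macrophages and leukocytes, and Schwann cells were also listed.

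Named genes followed a rule fixed before the data were examined. It took a panel (NFKBIA, TNFAIP3, ICAM1, SOD2, CCL2, CXCL1, CCL20, IRF1, NOS2, the insulin genes, PDX1, MAFA and SLC2A2), the 8 genes with the smallest p in each direction, and up to 3 called members per list. It also took the 5 differences with the smallest p in each direction and the 8 shared genes with the smallest rank sum. Placeholder symbols made of LOC or RGD and digits were passed over as not being gene symbols. Genes named outside the rule are said to be so. Coordinates of human genes come from GENCODE 29 on GRCh38; no rat coordinates are printed because the rat reference used here is another build than Rnor_6.0.

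Libraries, lists, main tests and most alternatives were fixed before the data were examined. The alternatives were DESeq2, RLE factors, library totals without TMM, limma-voom with sample weights, tests without the low-count filter, a mean count of 10 in an arm as the filter, 1 surrogate variable from sva, glmTreat against a fold change of 1.5, a z test on separate fits, and leaving out each library in turn. Added after seeing the data were leaving out islet libraries 9 and 13 together, entering them as a covariate, using the recovered reads, and leaving out single libraries in the list tests. Dixon's test for 4 values (critical value 0.829) was run on library totals and on log2(CPM + 1) of panel genes and of the genes with the smallest p.

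The tests were run on simulated counts with known changes. Among 9858 simulated rat genes, 34.0% of 100 genes changed by a log2 size of 1 and 88.0% of 100 changed by 2 were called, with 4 unchanged genes called. Among 11772 simulated islet genes the shares were 9.00% of 100 and 62.0% of 100, with 4 unchanged genes called. For the difference between systems, over 6618 genes, 65.9% of 123 genes changed by 2 were called, with 5 unchanged genes called. The analysis used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, sva 3.50.0, Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9. HLA genes entered the antigen presentation list only as group values.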

Results

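Gene expression was profiled by 3′ tag sequencing in rat insulinoma cells and in isolated human islets, each untreated or exposed for 3 h to 1 ng/mL IL-1β, a cytokine released by activated macrophages. Each of the 4 groups had 4 libraries. Totals were 5112483 to 7372764 counts in untreated and 5896265 to 8395162 in IL-1β-exposed rat libraries, and 6285589 to 10883570 and 8015338 to 11512141 in the corresponding islet libraries. The labels do not say whether libraries of a group came from separate cultures or donors, so the p-values measure the spread between these libraries, which may be technical. In rat libraries Ins1 alone took 4.17% of the counts. In islet libraries the most abundant transcripts were those of the exocrine enzymes and proteins CTRB2 (4.73%) and SPINK1 (4.42%), and acinar cell markers together took 14.3% ± 1.07 of the counts in untreated and 14.3% ± 1.53 in IL-1β-exposed libraries (SD, n = 4). The plot of principal components separated the arms in rat cells on its main axis, and in islets libraries 9 and 13 lay apart from the other 6.

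**Figure D1:**
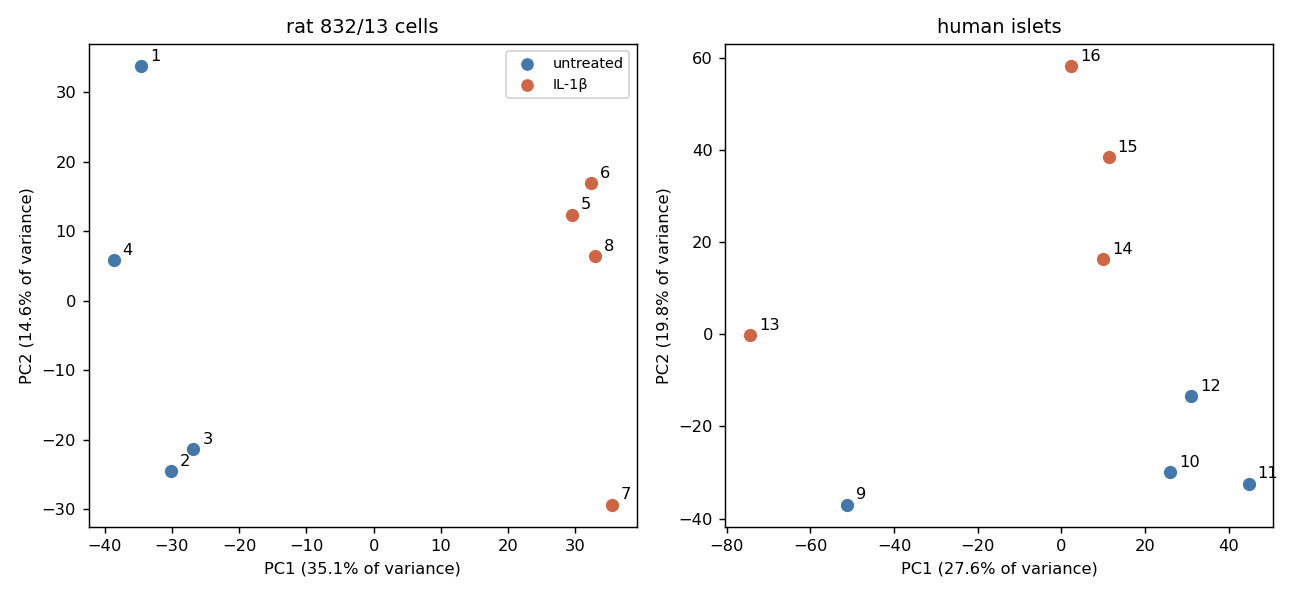
Principal components of log CPM values, with each point 1 library, coloured by arm and numbered as in the labels; axes give the share of variance. In rat cells the arms part along the axis with 35.1% of the variance, and in islets untreated library 9 and IL-1β library 13 lie apart from the other libraries along the axis with 27.6%.

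The comparison within rat cells asked which transcripts an acute IL-1β exposure changed in a beta cell line. The chemokine transcript Cxcl1, whose product attracts neutrophils, rose from 1.21 ± 0.633 to 1894 ± 235 CPM (SD, n = 4), a log2 fold change of 10.65 ± 0.29 (SE; adjusted p = 5.7e-10, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Zc3h12a, which encodes an RNase that degrades inflammatory mRNAs, rose by 7.13 ± 0.27 on the log2 scale (adjusted p = 1.8e-08). The ubiquitin-like modifier transcript Isg15 rose by 5.73 ± 0.23 (adjusted p = 5.2e-08). In the other direction, Nkx6-1, a transcription factor of mature beta cells, fell from 158 ± 26.0 to 36.6 ± 4.83 CPM, a log2 fold change of -2.11 ± 0.16 (adjusted p = 8.4e-06). Mafa, an activator of insulin transcription, fell from 153 ± 22.3 to 61.7 ± 8.30 CPM, a log2 fold change of -1.31 ± 0.16 (adjusted p = 0.000242).

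Of 9858 tested genes, 419 were higher and 119 lower with IL-1β, and 308 of the higher and 60 of the lower genes changed by at least 1 on the log2 scale. Scaling by library totals instead of TMM gave 354 higher and 169 lower, which moved the share of higher calls from 77.9% to 67.7%, and the median of all genes by -0.08. In the authors' deposited table, 665 genes were higher and 266 lower at an adjusted p under 0.05, and 534 of the 538 calls were also called there. Other genes with the smallest p among those that rose were Tnfaip3, a deubiquitinase that restrains NF-kB (log2 fold change 3.60 ± 0.16), the NF-kB subunit precursor Nfkb2 (4.51 ± 0.20), Parp14 (3.77 ± 0.18), the adaptor Traf3ip2 (2.48 ± 0.13) and the membrane fusion protein gene Stx11 (5.69 ± 0.33). Those that fell included the nuclear receptor Nr0b2 (-1.58 ± 0.16), Klhdc8a (-1.33 ± 0.17), the stress-inducible Sesn2 (-1.01 ± 0.13), the hormone gene Pthlh (-1.89 ± 0.24), Golim4 (-0.99 ± 0.15) and the small GTPase gene Rasd1 (-1.36 ± 0.21). Each of the 8 higher and 8 lower named genes with the smallest p lay above, or below, all untreated libraries in 4 of 4 IL-1β libraries. Choosing genes by their p favours such separation, so it is no further evidence. Nfkbia, the inhibitor that NF-kB itself induces, rose by 4.12 ± 0.61, Sod2, the mitochondrial superoxide dismutase, by 2.85 ± 0.22 and the transcription factor Irf1 by 3.45 ± 0.34. Tags of the adhesion molecule Icam1 numbered 3 in the untreated arm and 954 with IL-1β, a ratio of 290 with a counting interval of 98.9 to 1408. For the chemokine Ccl20, with 1 untreated count, the ratio was 102 (interval 18.0 to 4068).

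Insulin transcripts did not pass the test. Ins1 was at 42376 ± 8967 CPM untreated and 41271 ± 5012 with IL-1β (SD, n = 4; adjusted p = 0.954, edgeR), and Ins2 at 40.3 ± 18.9 and 35.2 ± 22.1 CPM (adjusted p = 0.931); the near-identical paralogs can share tags, so their split is uncertain. Pdx1, a beta cell transcription factor, had a log2 fold change of -0.37 ± 0.16 and lay below all untreated libraries in 4 of 4, with an adjusted p of 0.269. The glucose transporter Slc2a2 had a log2 fold change of 0.11 ± 0.21 (adjusted p = 0.890). Ccl2 had no counts in any library, and the inducible nitric oxide synthase Nos2 had 5 counts, in 1 IL-1β library, so neither was tested. Rat tag sites were not analysed here, so low expression and a missing or shared tag cannot be told apart for these genes. The plot of levels per library shows 8 genes of the panel in both systems.

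**Figure D2:**
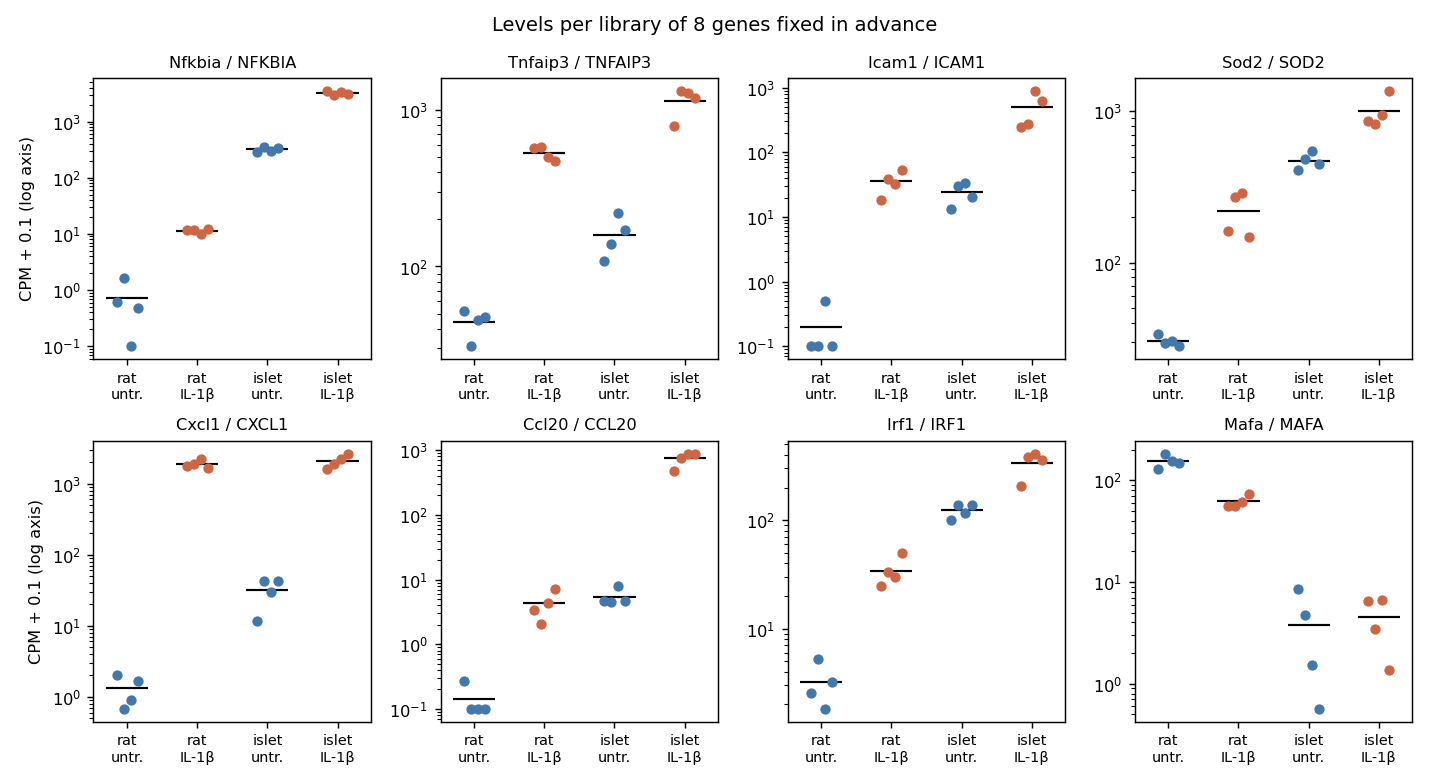
CPM + 0.1 on a log axis for 8 genes fixed in advance, with each point 1 library and each bar the mean of 4 libraries; blue is untreated and orange IL-1β. Cxcl1 means were 1.21 and 1894 CPM in rat cells and 31.4 and 2079 CPM in islets, while Mafa fell in rat cells and did not pass the test in islets.

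Among the gene lists fixed in advance, 18 had enough tested members in rat cells, of which 10 were called higher and 1 lower. All 8 tested chemokines rose (8 adjusted over the list alone, camera adjusted p = 4.0e-66), of 14 with a count. Some, such as Cxcl2 and Ccl20, passed the count filter only through their IL-1β libraries, which favours a rise among tested members. Among the 8 were Cxcl1, Cxcl3 (7.49 ± 0.50) and Cxcl2. The 3 untreated and 532 IL-1β counts of Cxcl2 gave a ratio of 162 (55.0 to 786). Of 21 NF-kB components and feedback genes, 15 rose and 6 did not pass (16 adjusted over the list alone; adjusted p = 3.8e-62), with Zc3h12a, Tnfaip3 and Nfkb2 leading. The median log2 fold change was 2.59, also with the 2 members at 0 in the untreated arm set at their bounds. Of 18 immediate early genes, 6 rose, led by Ier3 (3.25 ± 0.24), Sgk1 (3.43 ± 0.42) and Maff (2.96 ± 0.43), and Nr4a2 fell (9 and 2 adjusted over the list alone; adjusted p = 1.0e-05). Of 9 antigen presentation genes, B2m (0.90 ± 0.14), Psmb9 (1.62 ± 0.24), Nlrc5 (4.46 ± 0.88) and Psmb10 rose (7 adjusted over the list alone; adjusted p = 6.5e-07). Of 19 apoptosis and survival genes, 5 rose (7 adjusted over the list alone; adjusted p = 2.9e-06): the death receptor Fas (5.20 ± 0.56), the cell cycle inhibitor Cdkn1a (1.78 ± 0.20), Gadd45b (1.96 ± 0.25), the survival factor Mcl1 and the pro-apoptotic Bak1.

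Of 8 cytokines and growth factors, Il23a (2.91 ± 0.28), Csf1 (5.92 ± 0.48) and Bmp2 (1.23 ± 0.31) rose (3 adjusted over the list alone; camera adjusted p = 0.00145). Of 6 adhesion and matrix genes, Icam1 rose (2 adjusted over the list alone; adjusted p = 0.000349). Icam1, with 3 untreated counts, passed the count filter only through its IL-1β libraries, which favours a rise. The list had a median log2 fold change of 0.49 and a mean of 1.67. The same limit of the filter holds for Nlrc5 and Tlr2 in rat cells and for CSF3 in islets. Of 15 nitric oxide and oxidative defence genes, 4 rose (5 adjusted over the list alone; adjusted p = 0.00208): Sod2, Ass1, which makes an arginine precursor (1.42 ± 0.19), Gclc of glutathione synthesis (0.64 ± 0.15) and Txnip. Of 11 acute phase and STAT3 genes, Cebpd (1.61 ± 0.26), Socs3 (1.10 ± 0.18), C1s and Serping1 rose and Il6r fell by 0.85 ± 0.15 (5 and 1 adjusted over the list alone; adjusted p = 0.00944). Of 18 beta cell transcription factors, 7 fell and none rose, with a median of -0.50 (7 lower and 1 higher adjusted over the list alone; adjusted p = 2.5e-06). Nkx6-1, Mafa and St18 (-1.10 ± 0.19) led this list. All 11 calls held with an estimated correlation, with camera adjusted p values from 1.7e-05 (chemokines and NF-kB genes) to 0.0450 (acute phase genes).

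Beta cell function and secretion was not called (adjusted p = 0.130); of 33 members, the vesicle GTPase Rab3a (-0.99 ± 0.17) and the calcium receptor Casr (-1.05 ± 0.27) fell (2 adjusted over the list alone). In the interleukin-1 and Toll-like receptor pathway (adjusted p = 0.0545), the receptor Il1r1 (1.70 ± 0.17) and Tlr2, with a count ratio of 101 (27.7 to 841), rose among 14 members (2 higher and 1 lower adjusted over the list alone). In the unfolded protein response (adjusted p = 0.0984), Ppp1r15a (1.77 ± 0.32), Ddit3 (1.23 ± 0.25) and Eif2ak3 (0.91 ± 0.20) rose among 27 (6 higher and 1 lower adjusted over the list alone). No member passed, over all genes or adjusted over the list alone, in proliferation (17 members, adjusted p = 0.0545), glycolysis (11, 0.924), the nuclear encoded respiratory chain (19, 0.421) or heat shock genes (9, 0.924). The median and mean of glycolysis genes were positive and its test negative, and the respiratory chain had a median of 5.0e-05 with a negative mean and test. No mitochondrially encoded gene was in either count table used here. Cell type marker lists had under 5 tested members in rat cells and were not tested. Endothelial Pecam1 rose by 3.45 ± 0.60 among 3 tested members (1 adjusted over the list alone). The authors' deposited log2 fold change for Pecam1 was smaller, 1.14 ± 0.34. The authors' normalized values rest on another count, and 93.2% of their rat fold changes lay closer to 0 than the ratio of their arm means. No member of the other marker lists passed over all genes, although 1 of 2 Schwann cell markers passed adjusted over the list alone. Nr4a2, Psmb10, Mcl1, Bak1, Txnip, C1s and Serping1 were named after their values were seen.

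The calls of Bmp2, Casr, Gclc and Eif2ak3 ended when single libraries were left out, for Bmp2 each of libraries 2 to 8, for Casr 2, 3, 4, 5, 6 and 8, for Gclc 2, 3, 4, 5 and 8 and for Eif2ak3 1, 3, 5 and 8; the highest adjusted p values were 0.115, 0.126, 0.0762 and 0.0638. Without untreated library 4, 75 genes were lower instead of 119, and DESeq2 called 209 lower; a test against a fold change of 1.5 called 209 higher and 17 lower. Some lists without a call passed in other settings. The interleukin-1 and Toll-like receptor pathway was called higher with fry (adjusted p = 0.00258), on the reads recovered from the authors' table (0.0290) and without library 1, 3, 5 or 7 (0.0440 to 0.0482). Proliferation was called lower on the recovered reads (0.0473) and without library 2, 3 or 5 (0.00847 to 0.0482), and the unfolded protein response higher without library 2 or 7 (0.0264 and 0.0473).

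The comparison within human islets asked the same question in primary tissue, where beta cells lie among other endocrine and exocrine cells. The chemokine CCL20 rose from 5.33 ± 1.76 to 745 ± 188 CPM (SD, n = 4), a log2 fold change of 7.12 ± 0.27 (SE; adjusted p = 2.2e-07, edgeR quasi-likelihood test). CXCL1 rose from 31.4 ± 14.3 to 2079 ± 441 CPM (6.05 ± 0.34; adjusted p = 6.7e-06), and the cytokine IL1A from 0.849 ± 0.885 to 96.0 ± 6.13 CPM (6.89 ± 0.45; adjusted p = 6.7e-06). NFKBIA rose 10.0-fold, from 323 ± 31.3 to 3234 ± 218 CPM (3.33 ± 0.17; adjusted p = 5.7e-07). PRR15L fell from 66.5 ± 9.21 to 13.5 ± 5.03 CPM, a log2 fold change of -2.30 ± 0.27 (adjusted p = 0.00103).

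Of 11772 tested genes, 88 were higher and 3 lower with IL-1β, and 973 had an unadjusted p under 0.05. The authors' deposited table held 211 higher and 45 lower genes at an adjusted p under 0.05, and 90 of the 91 calls were also called there. DESeq2 run here gave 156 higher and 30 lower, which moved the share of higher calls from 96.7% to 83.9%. The small GTPase gene RND1 (4.38 ± 0.20), CXCL2 (5.07 ± 0.22), the apoptosis inhibitor BIRC3 (3.04 ± 0.18) and TNFAIP2 (3.67 ± 0.26) completed the 8 genes with the smallest p among those that rose. IER5L (-1.47 ± 0.28) and TTLL12 (-1.14 ± 0.22) were the other genes that fell. In the panel, TNFAIP3 (2.85 ± 0.25), ICAM1 (4.38 ± 0.43), CCL2 (3.13 ± 0.30), IRF1 (1.46 ± 0.23) and SOD2 (1.08 ± 0.21) rose, each above all untreated libraries in 4 of 4. The beta cell transcription factor MAFA was at 3.71 ± 3.56 CPM untreated and 4.39 ± 2.58 with IL-1β (adjusted p = 0.972). INS was listed at 0 in all 8 libraries; its last tag site gives a tag shared with INS-IGF2, and no change of INS could be assessed. PDX1 had 5 counts and NOS2 had 3, each in 1 untreated library, and SLC2A2 had 56 in 6 of 8 libraries, so these genes were not tested.

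On GRCh38, CCL20 lies on chromosome 2 from 227805739 to 227817564 and IL1A on the same chromosome from 112773915 to 112784590. The neutrophil chemokines CXCL1, at 73869393 to 73871242, and CXCL2, at 74097035 to 74099293, lie on chromosome 4. NFKBIA lies on chromosome 14 from 35401511 to 35404749, and so does TNFAIP2, from 103123442 to 103137439. BIRC3 lies on chromosome 11 from 102317450 to 102339403, RND1 on chromosome 12 from 48857145 to 48865898, and PRR15L on chromosome 17 from 47951967 to 47957878. IER5L is on chromosome 9 from 129175552 to 129178262 and TTLL12 on chromosome 22 from 43166622 to 43187133. All 11 are annotated as protein-coding. Each has at least 1 protein-coding transcript whose last tag site gives a tag found in no other gene.

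In islets 22 lists could be tested, and 8 were called higher and 0 lower by camera, which gave 3 lists a negative direction, none at an unadjusted p under 0.05. With an estimated correlation 7 were higher and 0 lower, and fry called 8 higher and 1, proliferation, lower. Of 16 chemokines, 11 rose and 5 did not pass (12 adjusted over the list alone; adjusted p = 4.7e-86), led by CCL20, CXCL2 and CXCL1. Of 22 cytokines and growth factors, 8 rose (15 adjusted over the list alone; adjusted p = 5.1e-45), among them IL1A, HBEGF (2.01 ± 0.23) and the colony stimulating factor CSF3, whose 2 untreated and 473 IL-1β counts gave a ratio of 209 (57.5 to 1728). Of 27 NF-kB components and feedback genes, 10 rose (14 adjusted over the list alone; adjusted p = 1.4e-45), led by NFKBIA, BIRC3 and TNFAIP2. Of 25 immediate early genes, SGK1 (1.65 ± 0.21), KLF6 (1.43 ± 0.22), IER5 (1.57 ± 0.25) and MYC rose (9 adjusted over the list alone; adjusted p = 3.9e-12); MYC was named after its value was seen. Of 18 adhesion and matrix genes, ICAM1 and the protease PLAU (3.37 ± 0.46) rose (7 higher and 1 lower adjusted over the list alone; adjusted p = 3.5e-09). Of 22 apoptosis and survival genes, the pro-apoptotic BBC3 (2.59 ± 0.39) rose (4 adjusted over the list alone; adjusted p = 7.4e-05). Of 20 acute phase and STAT3 genes, the pentraxin PTX3 (4.51 ± 0.71) rose (6 higher and 1 lower adjusted over the list alone; adjusted p = 0.000102). Of 21 interleukin-1 and Toll-like receptor pathway genes, the kinase IRAK2 (3.00 ± 0.30) rose (3 adjusted over the list alone; adjusted p = 0.0147), but this list call was lost, with adjusted p = 0.0618 with an estimated correlation. The other 7 calls held with an estimated correlation, with camera adjusted p values from 4.6e-05 (cytokines and NF-kB genes) to 0.0295 (adhesion and matrix genes).

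No call was made for antigen presentation (no member of 13 passed, over all genes or adjusted over the list alone; adjusted p = 0.585). Nitric oxide and oxidative defence was not called (adjusted p = 0.433), although the prostaglandin synthase PTGS2 (3.10 ± 0.33) and SOD2 rose among 20 (2 higher and 1 lower adjusted over the list alone). Beta cell transcription factors were not called (adjusted p = 0.433), and among 20 members FOXA2 rose by 1.08 ± 0.21 (2 adjusted over the list alone). Beta cell function and secretion had no passing member among 29 (0 adjusted over the list alone, camera adjusted p = 0.668). This list, with INS listed at 0, took 0.118% ± 0.0547 of the counts untreated and 0.120% ± 0.0477 with IL-1β (SD, n = 4). Such a small share limits what its test can show. Ductal cell markers were not called (adjusted p = 0.433), with a median of -0.13, a positive mean and a positive test, and the metalloproteinase MMP7 rose by 1.86 ± 0.31 among 14 (3 adjusted over the list alone). Ductal markers took 0.199% ± 0.0288 of the counts untreated and 0.471% ± 0.181 with IL-1β (SD, n = 4). MMP7 alone, taken apart after the values were seen, went from 0.110% ± 0.0189 to 0.387% ± 0.167, and the other ductal markers from 0.0888% ± 0.0127 to 0.0838% ± 0.0144, so the rise in this share was that of MMP7. No member passed, over all genes or adjusted over the list alone, in the unfolded protein response (25 members, adjusted p = 0.465), glycolysis (16, 0.194), the nuclear encoded respiratory chain (17, 0.194), proliferation (10, 0.465), markers of alpha, delta and PP cells (8, 0.504), of acinar cells (15, 0.541) or of stellate cells and fibroblasts (10, 0.504); among 11 heat shock genes (adjusted p = 0.407) 1 passed adjusted over the list alone. Endothelial, leukocyte and Schwann cell marker lists had 3, 2 and 1 tested members, none of which passed.

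Single libraries ended the islet calls of SOD2 (9 to 12, 15 or 16 left out), IER5L (9, 10, 12, 14, 15 or 16), TTLL12 (9 or 11 to 16), FOXA2 (9, 10 or 12 to 16), MMP7 (10, 11 or 16) and PTX3 (9, 12 or 16), with adjusted p values up to 0.126, 0.109, 0.125, 0.144, 0.0766 and 0.0589. The count of lower genes was 13 without untreated library 9, 1 without library 12, 14 or 16, and 12 without libraries 9 and 13, against 3; a surrogate variable gave 135 higher and 16 lower, and a test against a fold change of 1.5 gave 52 higher and 1 lower. Ductal cell markers were called higher without library 13 (adjusted p = 0.0196), and glycolysis genes without library 9 (0.0267).

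**Figure D3:**
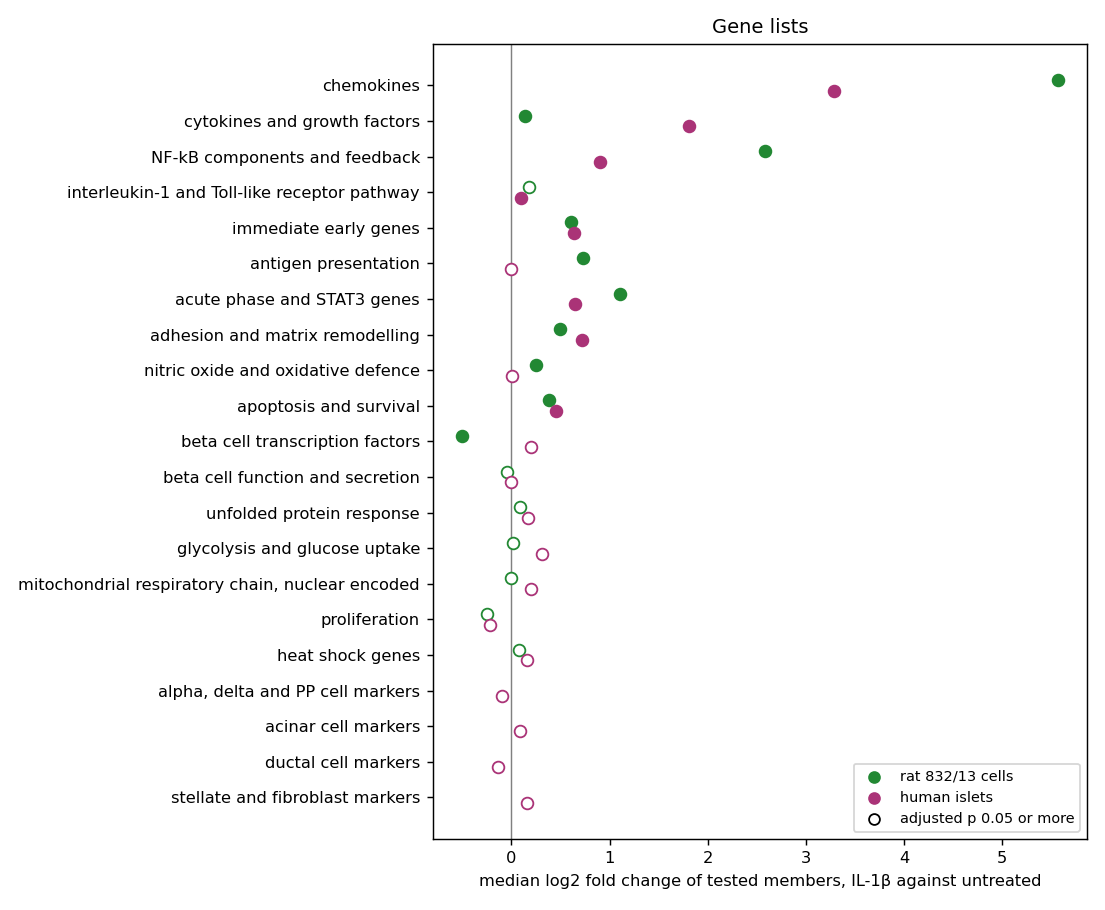
Median log2 fold change of the tested members of gene lists, IL-1β against untreated, in rat cells (green) and islets (purple); filled points are lists with a camera adjusted p under 0.05. Chemokines had medians of 5.56 in rat cells and 3.29 in islets, and beta cell transcription factors -0.50 and 0.20.

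The comparison of both systems asked which responses to IL-1β were shared and which differed. ISG15 had a log2 fold change of 5.73 in rat cells and 0.03 in islets, a difference of -5.73 ± 0.33 (islets minus rat cells, SE, n = 4 per group; adjusted p = 1.2e-08, edgeR interaction term). CXCL1 rose in both systems, and its fold change was lower in islets by a log2 difference of -4.64 ± 0.53 (adjusted p = 3.8e-05). FOXA2, a transcription factor of endocrine and endodermal cells, fell in rat cells (-0.74) and rose in islets (1.08), a difference of 1.78 ± 0.28 (adjusted p = 0.00105). RND1 had a higher fold change in islets, by a log2 difference of 3.10 ± 0.44 (adjusted p = 0.000596).

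Of 6862 matched genes, 121 had a different response, 26 with the higher fold change in islets and 95 with the higher in rat cells; 782 had an unadjusted p under 0.05. Higher in islets were also SESN2 (1.95 ± 0.27) and RASD1 (2.42 ± 0.36), which fell in rat cells and had islet log2 fold changes of 0.98 and 1.10 that did not pass, and the lipid transporter MFSD2A (3.16 ± 0.68), which passed in neither system. Higher in rat cells were SNX11 (-3.14 ± 0.30), SEMA4A (-5.03 ± 0.54) and STX11 (-4.08 ± 0.45), of which only STX11 also passed in islets (1.65 ± 0.28). STAP2 differed as well (adjusted p = 1.7e-05): its rat symbol Stap2 had 0 counts in the untreated rat libraries and was at least 48.2-fold higher with IL-1β, while islets had 61.1 ± 13.3 and 64.2 ± 10.1 CPM. In the panel, SOD2 (-1.82 ± 0.32, adjusted p = 0.00392) and IRF1 (-2.02 ± 0.42, adjusted p = 0.0134) had smaller fold changes in islets. Their untreated levels were higher there. SOD2 went from 473 to 1000 CPM in islets and from 30.1 to 218 CPM in rat cells. IRF1 went from 123 to 338 CPM in islets and from 3.10 to 34.2 CPM in rat cells. The differences for NFKBIA (-0.84 ± 0.53), TNFAIP3 (-0.80 ± 0.33), ICAM1 (-3.68 ± 1.40), CCL20 (0.97 ± 1.59) and MAFA (1.48 ± 0.71) did not pass, with adjusted p values of 0.599, 0.331, 0.0814, 0.961 and 0.437. For ICAM1 the difference passed with DESeq2 (adjusted p = 0.00852), without islet library 9 (0.0480) or 15 (0.0300) and on recovered reads (0.00893).

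Higher with IL-1β in both systems were 25 genes, against 2.24 expected for independent lists of 301 and 51 genes, an odds ratio of 22.7 (95% interval 12.4 to 41.5; p = 3.7e-21, Fisher's exact test, two-sided). The 8 with the smallest rank sum were CXCL1, TNFAIP3, ZC3H12A, CXCL3, BIRC3, CXCL2, ICAM1 and the kinase MAP3K8. In islets ZC3H12A rose by 3.87 ± 0.42, CXCL3 by 6.02 ± 0.46 and MAP3K8 by 3.59 ± 0.31, and in rat cells BIRC3 rose by 5.57 ± 0.49 and MAP3K8 by 4.37 ± 0.40. No gene was called lower in both systems by edgeR, by limma-voom or by DESeq2, with 88 rat and 1 islet call among matched genes, and 19 had a negative fold change with an unadjusted p under 0.05 in both. Without the low-count filter 1 gene, NR0B2, was lower in both (-1.57, adjusted p = 2.3e-07, and -2.28, adjusted p = 0.0259). FOXA2 was the 1 gene called in opposite directions, and its islet call ended when library 9, 10, 12, 13, 14, 15 or 16 was left out. Across genes, which are not independent replicates, the fold changes had a Pearson r of 0.238 and a Spearman rho of 0.0875. Of 301 genes higher in rat cells, 60.5% had a positive islet fold change against 50.9% of all matched genes; of the 51 genes higher in islets, 84.3% had a positive rat fold change. The count of different responses was 248 with DESeq2 and 228 with a z test on separate fits. It was 200 on recovered reads and 61 against a fold change of 1.5. Of these, 78, 83, 52 and 7 had the higher fold change in islets, against 26 in the reported fit. Without islet library 9 that number was 47.

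**Figure D4:**
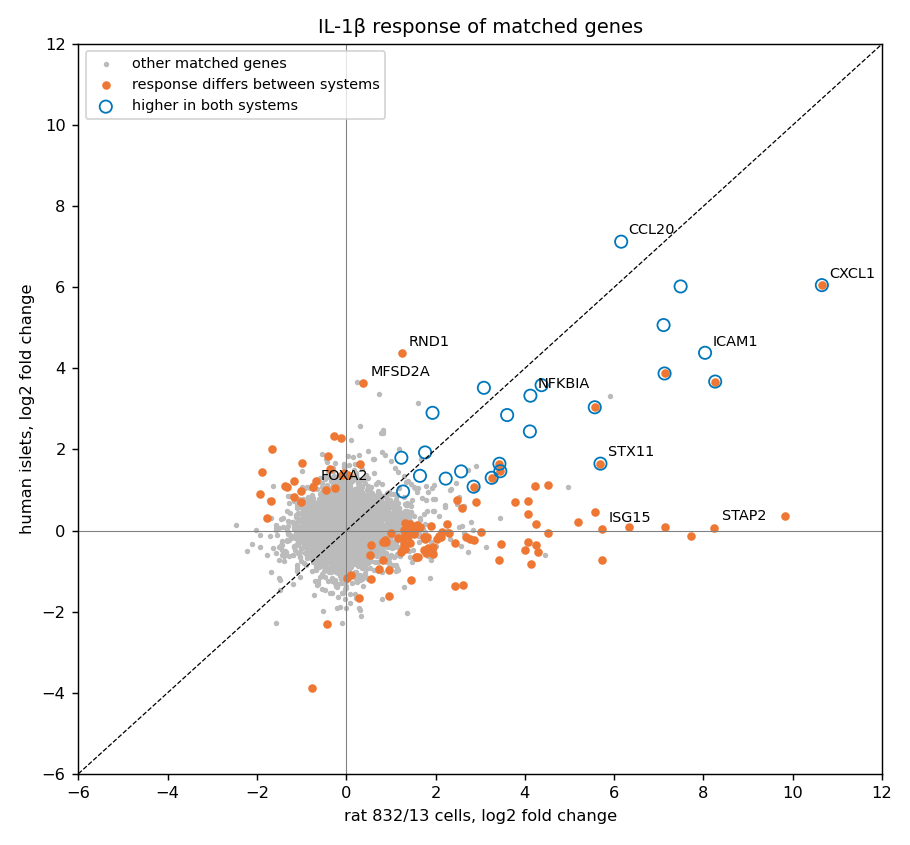
Log2 fold change with IL-1β of matched genes, rat cells on the horizontal and islets on the vertical axis; orange points are the 121 genes whose response differed, open circles the 25 genes higher in both systems, and the dashed line marks equal change. ISG15 lies at 5.73 on the rat and 0.03 on the islet axis, and fitted values of genes with no counts in an arm, such as STAP2, are no bound.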

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

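The comparison of depths between the systems was chosen after the result was seen; the other tests here were set out before their results were examined. Of 93 groups of 4 libraries tested with Dixon's test, 7 held a value far from the other 3, where chance gives about 1 in 20 groups. In 5 of the 7 the value was the highest of a gene at or near 0 counts: Icam1 at 0.397 CPM in untreated rat library 3, Ccl20 at 0.175 CPM in untreated rat library 1, Nos2 at 0.637 CPM in IL-1β rat library 5, NOS2 at 0.464 CPM in untreated islet library 12 and PDX1 at 0.677 CPM in untreated islet library 10. Pthlh was at 4.27 CPM in IL-1β rat library 6, the lowest of its arm. CCL20 was at 7.97 CPM in untreated islet library 11, the highest of its arm. Counts of rat libraries in the human table came to 9.03% of their own totals on average, and counts of islet libraries in the rat table to 3.76%; the comparisons do not use them.

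The interaction test singled out 13 named genes whose response to IL-1β differed between the systems, as log2 fold change in islets minus that in rat cells. Higher in islets were SESN2 (1.95), which encodes a stress sensor upstream of mTORC1, RND1 (3.10), RASD1 (2.42), FOXA2 (1.78) and MFSD2A (3.16). Higher in rat cells were the interferon-stimulated ISG15 (-5.73), the sorting nexin SNX11 (-3.14), the adaptor STAP2 (-8.11, a fitted value and no bound, since the untreated rat arm was at 0), SEMA4A (-5.03), STX11 (-4.08), SOD2 (-1.82), CXCL1 (-4.64) and IRF1 (-2.02).

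A broader pattern lay behind these genes: 91 genes passed in islets and 538 in rat cells. Lower depth is argued against, since the median islet total was 1.25 times the rat one. Wider spread between islet libraries, with a common biological coefficient of variation of 0.417 against 0.289, would lower the number by itself. Of 389 rat calls tested in both systems, 115 would pass at the rat fold change with the islet standard error. In islets 26 did pass, 25 of them in the same direction. This argues against wider spread as the whole cause, although choosing genes by their rat result inflates the 115. The median log2 fold change of the 301 genes higher in rat cells was 1.34 there and 0.11 in islets, a ratio of 0.0800 (bootstrap interval 0.0485 to 0.151). The bootstrap resampled genes and not libraries, so its interval leaves out the spread between libraries. Smaller fold changes in islets would give such a ratio, but choosing genes by their rat result inflates the rat side. For the 51 genes higher in islets the rat median was 1.23 against 1.87, a ratio of 0.658. Neither ratio is free of the choice of genes, so a general reduction in islets was not shown. Species, mixture of cell types and RNA extraction changed together between the systems and stay open as sources of any smaller fold changes in islets.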

How the results depend on the processing

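The settings chosen after the data were seen were leaving out islet libraries 9 and 13, entering them as a covariate, the reads recovered from the authors' table, and leaving out single libraries in the list tests. No call that passed in both the reported and an alternative fit changed sign, and no named gene's call reversed. Genes higher and lower in rat cells, 419 and 119, were 209 and 17 against a fold change of 1.5, and 209 were lower with DESeq2. Islet counts of 88 and 3 were 156 and 30 with DESeq2, 168 and 34 without the low-count filter, 135 and 16 with a surrogate variable, 52 and 1 against a fold change of 1.5, and 146 and 17 with libraries 9 and 13 as a covariate; lower genes numbered 12 without both libraries and 6 on recovered reads. The difference between systems, 121 genes, was 248 with DESeq2, 228 with a z test, which leaves out genes without a standard error, 200 on recovered reads and 61 against a fold change of 1.5. Genes lower in both numbered 1 without the filter. A stricter null explains the smaller counts against a fold change of 1.5; otherwise the cause was not tested. Leaving out each library in turn gave 332 to 409 higher and 75 to 100 lower genes in rat cells, 60 to 100 and 1 to 13 in islets, 19 to 27 higher and 0 to 0 lower in both, 89 to 156 differences, 11 to 13 called lists in rat cells and 8 to 9 in islets. Among named genes, a fold change of 1.5 ended the calls of 11 of 54 in rat cells and 8 of 29 in islets, and leaving out 1 library ended at most 4 in rat cells and 6 in islets. With RLE factors and with limma-voom the side of the threshold held for all named genes in both systems. No paired analysis was run, because the groups share no library numbers and the labels link no libraries across the arms. At the given depth and spread, 9.00% of simulated changes of 1 on the log2 scale were called in islets and 34.0% in rat cells; depth and spread were not tested apart there.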

Other observations

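The tests of tag sites and the genes named in this part were chosen after the result was seen. Several transcripts outside the fixed rule added to the rat response. The lymphocyte activation marker Cd69 had 0 counts in the untreated arm and was at least 281-fold higher with IL-1β (908 counts), the neuropeptide gene Calcb at least 144-fold higher (476 counts) and the GTPase gene Gbp5 at least 91.2-fold higher (291 counts). Chemokines that signal through CXCR3 rose as well, Cxcl11 from 1.86 ± 1.29 to 58.5 ± 10.9 CPM (SD, n = 4) and Cxcl10 from 0.615 ± 0.796 to 12.6 ± 5.50 CPM, with adjusted p values of 3.9e-05 and 0.00352 (edgeR). The other beta cell transcription factors that fell were Foxo1 (-1.68 ± 0.31), Rfx6 (-1.12 ± 0.24), Foxa2 (-0.74 ± 0.16) and Pax6 (-0.51 ± 0.12). Their edgeR adjusted p values were 0.00560, 0.0131, 0.0150 and 0.0300. Each lay below all untreated libraries in 4 of 4 IL-1β libraries, which choosing genes that passed favours.

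In islets the neutrophil chemokines CXCL8 and CXCL6 rose by 3.45 ± 0.28 and 4.90 ± 0.36 on the log2 scale (SE; adjusted p = 8.0e-05 and 9.0e-05, edgeR). The cytokines CSF2 (6.14 ± 0.76), IL1B (5.84 ± 0.74) and TNF (4.01 ± 0.57) rose from 0.398, 0.458 and 0.727 CPM to 27.3, 30.2 and 11.6 CPM. The interferon gamma receptor subunit IFNGR2 rose in both systems, by 1.93 ± 0.21 in islets and 1.77 ± 0.18 in rat cells.

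Islet libraries 9 and 13 deviated from their arms together, with a correlation of deviations across genes of 0.462. Greater depth is argued against: after thinning all islet libraries to 6285589 counts the correlation was 0.472, and the highest of the other pairs across arms 0.220. A different share of acinar RNA alone is argued against, since acinar markers had a median log2 difference of -0.31 ± 0.19 (bootstrap SE; 9 and 13 against the other 6) while other types lay on both sides of 0: beta cell function 0.63 ± 0.16, ductal -0.84 ± 0.30 and stellate markers -1.51 ± 0.38. Among the other pairs across arms, 10 and 14, 11 and 15, and 12 and 16 correlated at 0.118, 0.165 and 0.190, and 11 and 14 at 0.179. Acinar markers took 13.0%, 14.0%, 15.4% and 14.8% of the counts in libraries 9 to 12 and 12.3%, 14.1%, 15.8% and 15.1% in libraries 13 to 16. In rat cells the highest correlation across arms of each untreated library, 1 to 4, was with libraries 5, 6, 7 and 8 in turn (0.164, 0.101, 0.153 and 0.0830). The labels link none of these libraries, and a link would change the spread that the tests use. The labels give no donor or preparation, so neither was tested as an explanation, and a shared origin of libraries 9 and 13 may remain among the open ones.

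INS and SST were at 0 in all 8 islet libraries, although the hormones they encode are made in islets. A candidate explanation is the tag site. Some genes had no CATG site in any protein-coding transcript, or only last sites whose tags of 25 bases were shared with another gene. These were listed at 0 in 70.1% of 939 cases, against 15.5% of 17577 genes with a unique tag in at least 1 such transcript, a ratio of 4.52. INS shares its tag with INS-IGF2, and the SST transcript has no site. This is a trend over genes and not a rule, since CXCL10 has a unique tag and was also at 0. The beta cell genes PDX1 and SLC2A2 were also classed with a unique tag, and had only 5 and 56 counts over the 8 libraries. Of the 2 protein-coding transcripts of SLC2A2, however, 1 has no site, so a missing site stays possible for SLC2A2. Rat tag sites were not analysed here.

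Other splits of the same libraries tested whether chance can be excluded. In rat cells the real split gave 538 changed genes and the highest of the other splits 7, with 1 of 35 splits as high; in islets the real split gave 91 and the highest other 1, again 1 of 35. This argues against chance for these counts, at the smallest share that 35 splits can give. It takes the libraries as independent, which the labels do not show. Nor can it tell treatment from a difference in culture or batch between the arms. For the response difference the real arms gave 121 genes and the highest of the other draws 78, and for genes changed the same way in both systems 25 and 0. Of these 100 draws, 92 kept the real arms of neither system and so held at most part of a response to compare. They do not show whether a difference or an overlap exceeds chance. Chance cannot be excluded by all splits for the number of lists called: 2 of 35 rat splits gave at least the real 11, the highest other 12, and 7 of 35 islet splits gave at least the real 8, the highest other 11. The other splits that reached these numbers all kept 3 of 4 libraries of a real arm together and still held part of the response. The 18 splits with 2 libraries of each arm on either side, set apart after the result was seen, gave at most 2 lists in rat cells and 6 in islets, but are too few for a share under 0.05. In islets those that kept libraries 9 and 13 on the same side gave 2 to 6 lists. Those that parted libraries 9 and 13, as the real arms do, gave 0 or 1. The smallest list adjusted p was 4.0e-66 in the real rat split and 6.2e-09 in the others, and 4.7e-86 and 2.0e-10 in islets.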
